A study of Homo sapiens with 50 samples.

How the data were processed

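The series holds 50 chromatin immunoprecipitation sequencing (ChIP-seq) libraries from DLD-1 cells, a human colorectal adenocarcinoma line. Per the labels, the cells carried the plant F-box protein OsTIR1. An auxin-inducible degron (AID) tag on a protein lets OsTIR1 direct its degradation once auxin is added, and the labels' protocol gives 500 µM auxin. Cells were fixed with 1% paraformaldehyde for 10 min, and fixed mouse fibroblasts were added as a spike-in, per the labels' protocols. The submitters' processing notes name the builds hg38 and mm10 and the tools cutadapt 1.14, Bowtie2 2.2.6 and deepTools 3.1.1, with no role or order.

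Both files analysed here are lists for the whole series, with 6481 rows and 6 columns each and no value for any library. One holds gene intervals and the other a single pause site of 1 bp for each of the same genes, deposited by the authors as hg38 coordinates in bp, per the names they gave the lists and the submitters' processing notes. How the pause sites were called, from which assay and from how many samples is not given in the sources used here. The lists carry no score, so the depth behind each site is unknown. The signal of the 50 libraries was not analysed here. No comparison between antibodies, lines, treatments or times was therefore made, and no mean over libraries, replicate error or depth per library can be stated.

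Coordinates were converted to 1-based positions. The pause distance was the number of bp from the gene's listed 5' end to its pause site along the gene's strand, so that 0 places the site on the first listed base. Rows of both lists were joined by their Ensembl identifier. The lists give identifiers without symbols, and the gene table used for names (RefSeq, assembly GRCh38.p14, the same primary coordinates as hg38) holds 0 Ensembl identifiers. Names were therefore taken by position. An entry received a symbol when exactly 1 RefSeq gene had its 3' end, read on the entry's strand, within 50 bp of the entry's 3' end and covered at least 50% of the entry. This named 5822 of the 6481 entries. After all entries were shifted by 1000000 bp downstream or upstream, the same rule named 6 and 4 of them. A second rule, a reciprocal overlap of 80% with no other gene over 50%, named 5607 entries, and no entry received different symbols from the rules. RefSeq gene extents include all annotated transcripts and carry no strand or exons here, so strand came from the authors' list, 5' ends were compared with the outermost start of the gene, and exons, introns and untranslated regions were not assigned.

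Analyses were run in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The gene lists, their tests, the rule for named genes and most alternative settings were fixed before the data were examined. The naming rule, its second form, the classes of 5' end offset, the background of genes without a close neighbour and all tests of gene families, chromosomes and neighbours were chosen after seeing the data, the naming rule after match rates and list counts under the second form had been seen. The 21 lists were study targets, elongation factors, immediate early genes, heat shock genes, ribosomal proteins, translation factors, replication-dependent histones, Wnt targets, p53 targets, oxidative phosphorylation, proteasome, zinc finger genes, splicing factors, DNA replication, mitosis, cholesterol synthesis, glycolysis, the integrated stress response, and markers of colon epithelium, fibroblasts and blood. Membership in the authors' list was tested with two-sided Fisher's exact tests against all RefSeq protein-coding genes on the numbered, X and Y chromosomes. Lists with at least 5 entries were tested for pause distance with a two-sided permutation test of the difference in medians between the list and all other entries, with 100000 resamples. Distance and length were related by Pearson's r and Spearman's rho with as many permutations. Benjamini-Hochberg adjustment was made over the lists, with a threshold of 0.05. Intervals of medians came from 10000 bootstrap draws over entries for all entries and 2000 for lists and offset classes, and intervals of shares are 95% Wilson intervals. Genes are not independent replicates, and all p-values and intervals rest on variation between genes, not between samples.

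The named genes were the 10 entries with the largest and the 10 with the smallest pause distance (ties by symbol), every study target in the list, and for each list the members with the smallest, middle and largest distance. Of the genes this rule names, 2 are not reported here. The tests were checked on simulated data. Of 2000 RefSeq genes whose 5' end was moved by up to 300 bp, 98.1% were named correctly and 0% wrongly. Only the 5' end was moved, so the gene of origin remained a candidate by its 3' end. The rule names only unique matches, so a wrong name could hardly arise, and the 0% does not measure wrong names in the data. In the data, 20.3% of named entries had a 5' end over 300 bp downstream of RefSeq's, beyond the simulated range. Of 100 random lists of 10 entries, 6 passed the unadjusted threshold unshifted, 10 when shifted by 10 bp and 27 when shifted by 20 bp. Of 100 random lists of 20 entries, 3 passed the unadjusted threshold unshifted, 22 when shifted by 10 bp and 65 when shifted by 20 bp. Of 100 random lists of 150 entries, 6, 96 and 100 did. Of 100 random lists of 20 genes, 5 passed the membership test.

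Planned tests of the base at the pause site, of core promoter elements and of GC content need a genome sequence and were not run. Alternatives covered the range of distances, the strand, the agreement of the 5' end with RefSeq, means in place of medians, the background of the membership test and the naming rule.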

Results

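The study addressed how SPT6, a histone chaperone and elongation factor that travels with RNA polymerase II (Pol II), acts in the release of paused Pol II and in the recruitment of the PAF1 complex (PAF1C). The 50 ChIP-seq libraries fell into 32 groups by antibody, cell line, treatment and time, 18 of them with 2 libraries and 14 with 1. Total Pol II (RPB1 N-terminal antibody) accounted for 21 libraries, PAF1 for 8, and SPT6, LEO1, RTF1 and NELF-C for 4 each. CDC73 and WDR61 had 2 libraries each, and 1 library was input. By line, 30 libraries came from SPT6-AID cells, 9 from PAF1-AID cells, 4 each from the SPT6/PAF1 and SPT6/NELF-C double-degron lines, and 3 from the parental line. Treatments were vehicle for 2 h or auxin for 0, 2 or 6 h. The signal of these libraries was not analysed here. The measurements below concern the authors' list of genes and of their pause sites in DLD-1 cells, the positions just downstream of gene starts at which Pol II halts before productive elongation.

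The authors' list held 6481 genes of at least 3005 bp, of which 5822 could be named and all of those were protein coding. They included genes of transcription elongation, cell division and metabolism, and 0 of 12 fibroblast and 0 of 12 blood markers. The genes lay on 24 chromosomes, 3357 on the plus and 3124 on the minus strand, with a median length of 35481 bp. None overlapped another entry, and the smallest gap between neighbours was 825 bp, between a head-to-head pair. The smallest gap was 1502 bp for tail-to-tail pairs and 1527 bp for tandem pairs. Among RefSeq protein-coding genes of at least the same length, 16.8% (1186 of 7068, 95% Wilson interval 15.9 to 17.7%) were listed where another protein-coding gene overlapped or lay within 1000 bp. Without such a neighbour 42.0% were listed (4636 of 11026, 41.1 to 43.0%; Fisher's exact test, p = 9.64e-292).

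Of the 21 gene lists, 12 were listed more often than other protein-coding genes and 3 less often. The immediate early genes, which respond within minutes to growth factors, had 17 of 24 members in the list (70.8%), against 29.0% of all other protein-coding genes. Mitosis genes had 14 of 20, integrated stress response genes 10 of 15 (66.7%), elongation factors 17 of 26 (65.4%) and translation factors 14 of 22 (63.6%). Cholesterol synthesis genes had 11 of 18 (61.1%), and the Wnt target and p53 target lists had 11 of 20 each (55.0%). Proteasome subunits had 20 of 39 (51.3%), oxidative phosphorylation genes 33 of 73 (45.2%), ribosomal proteins 37 of 88 (42.0%) and zinc finger genes 181 of 477 (37.9%).

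These 12 lists passed the two-sided Fisher's exact test, with Benjamini-Hochberg adjusted p from 0.000192 for immediate early and zinc finger genes to 0.0335 for the Wnt and p53 targets. Another 3 lists were listed less often. Replication-dependent histones, which encode the bulk histones of S phase, had 0 of 69 members in the list (Fisher's exact test, adjusted p = 1.47e-09), and fibroblast and blood markers had 0 of 12 each (adjusted p = 0.0335, 95% Wilson upper bound 24.2%). Only 6 of the 69 histone genes and 8 of the 12 blood markers were at least as long as the shortest entry, 3005 bp. The calls for these 2 lists therefore do not separate gene length from other reasons for absence. The other 6 lists did not pass Fisher's exact test: study targets (5 of 9, adjusted p = 0.147), heat shock genes (10 of 20, 0.0636), splicing factors (17 of 40, 0.0927), DNA replication (11 of 24, 0.0927), glycolysis (7 of 17, 0.303) and colon epithelium (8 of 20, 0.324). Against protein-coding genes of at least 3005 bp, 12 of the 21 lists passed Fisher's exact test, and the calls for histones (0 of 6, adjusted p = 0.208), p53 targets (11 of 20, 0.0773) and blood markers (0 of 8, 0.0855) ended. With the reciprocal-overlap names 12 lists passed Fisher's exact test, and the calls for ribosomal proteins (adjusted p = 0.0511), p53 targets (0.161) and oxidative phosphorylation (0.0763) ended. Against genes of that length without a protein-coding neighbour within 1000 bp, a background chosen after the data were seen, the calls for Wnt targets (10 of 15, Fisher's exact test, adjusted p = 0.0780), zinc finger genes (159 of 337, 0.0700) and histones (0 of 2, 0.538) ended. Against all RefSeq genes, coding or not, those for fibroblast and blood markers ended (Fisher's exact test, adjusted p = 0.621 each). The 6 lists without a main call all passed Fisher's exact test there (adjusted p 1.47e-07 for splicing factors to 0.000926 for study targets). That background held 59679 genes, 20037 of them protein coding, whereas all named entries were coding. Lists of coding genes are therefore raised against it by their biotype alone. These 6 passes do not show that the lists stand out among coding genes. Heat shock genes, splicing factors and DNA replication also passed against genes without a close neighbour. A further 48 genes of the lists, 32 of them zinc finger genes, overlapped an unnamed entry and were counted as not listed.

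**Figure D1:**
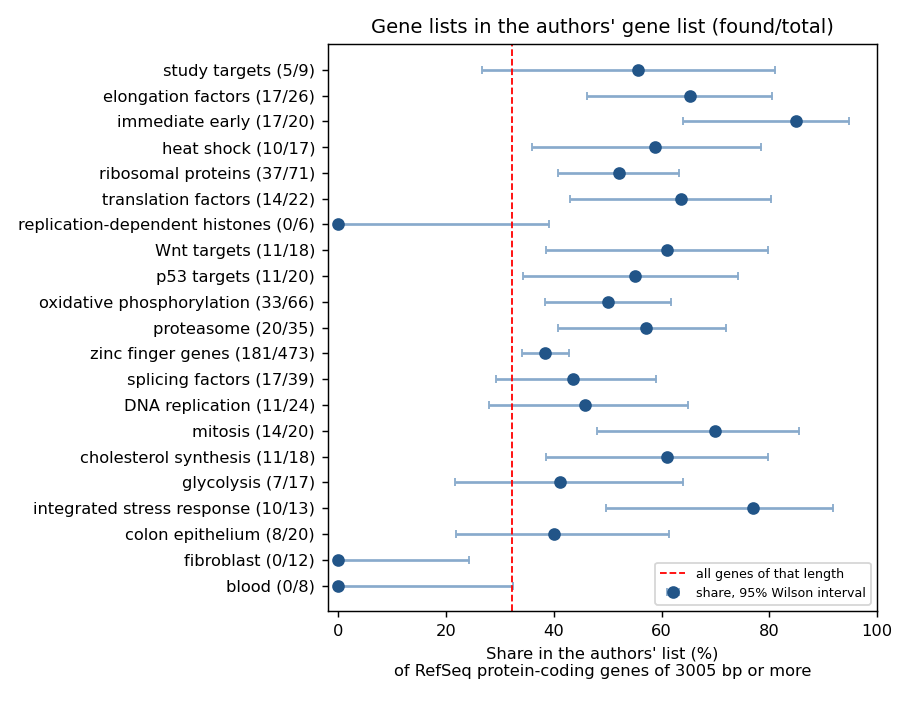
Share of each gene list found in the authors' list (x axis, % of RefSeq protein-coding genes of at least 3005 bp), with points as shares, bars as 95% Wilson intervals and the dashed line as the share of all such genes. Immediate early genes stood at 85.0% (17 of 20), while histones, fibroblast and blood markers stood at 0%.

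Pause sites lay a median of 52 bp downstream of the listed 5' end (95% bootstrap interval 51 to 53, 6481 genes), with quartiles of 38 and 84 bp. The most frequent distance was 41 bp, found in 141 genes, and 19.1% of the sites lay at 40 to 49 bp. Of all sites, 53.4% (95% Wilson interval 52.1 to 54.6%) lay at 20 to 60 bp, and 81.3% (80.4 to 82.3%) at up to 100 bp. A tail of 1210 genes (18.7%, 17.7 to 19.6%) had sites farther than 100 bp, up to 299 bp, and 459 genes (7.08%, 6.48 to 7.73%) had sites under 20 bp. The middle 95% of genes spanned 8 to 251 bp. The median was 52 bp on either strand, and the means differed by 0.457 bp between plus and minus strand genes (two-sided permutation test, p = 0.744). The spread quoted is between genes, since the list gives 1 site per gene and no replicate.

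**Figure D2:**
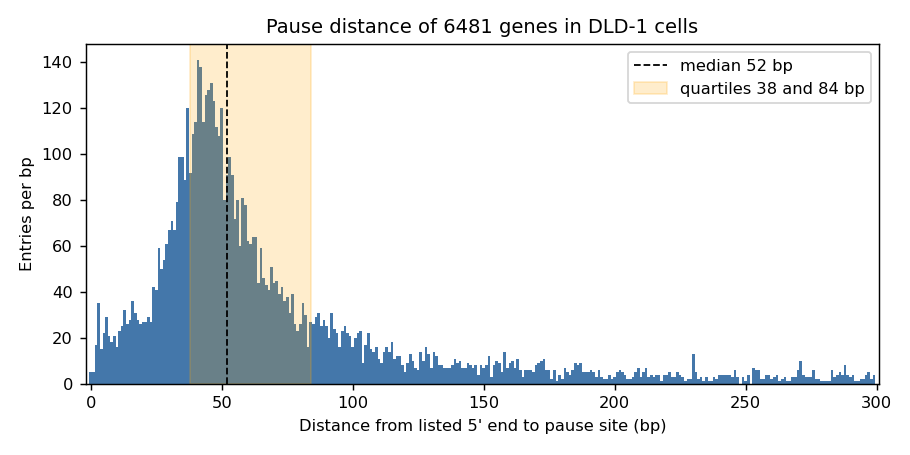
Number of genes (y axis) at each distance in bp from the listed 5' end to the pause site (x axis), with the median of 52 bp dashed and the quartiles of 38 and 84 bp shaded. Counts peak at 41 bp and thin out to the last listed distance of 299 bp.

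Among the proteins that the study tagged or immunoprecipitated, or that belong to PAF1C, 5 of 9 genes were in the list. The gene for CTR9, a PAF1C scaffold subunit (ENSG00000198730.9, hg38 chromosome 11, plus strand, 5' end 10751278), had its pause site at 10751313, a distance of 35 bp. LEO1 (ENSG00000166477.13, chromosome 15, minus strand, 5' end 51971746) had its site at 51971708, 38 bp downstream. For SKIC8, whose older symbol is WDR61 (ENSG00000140395.9, chromosome 15, minus strand, 5' end 78299607), the site was at 78299549, 58 bp downstream. RTF1 (ENSG00000137815.15, chromosome 15, plus strand, 5' end 41417132) had a site at 41417263, 131 bp downstream, and CDC73 (ENSG00000134371.14, chromosome 1, plus strand, 5' end 193122068) one at 193122338, 270 bp downstream. The latter lay beyond the range of the middle 95% of genes, 8 to 251 bp. SUPT6H (which encodes SPT6), PAF1, POLR2A (which encodes RPB1) and NELFCD (which encodes NELF-C) were not among the named entries, and none of the 659 unnamed entries overlapped them. Of the 9 genes, 3 had no protein-coding neighbour within 1000 bp, and all 3 were listed. The 4 missing genes therefore had such a neighbour, as do genes listed at 16.8% against 42.0% without one. Their absence does not show that they lack a pause site.

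No gene list passed the test for a difference in pause distance from the remaining genes. The lowest medians were those of heat shock genes (37 bp, 10 genes), colon epithelium markers (38 bp, 8 genes; their mean lay 14.3 bp above that of the others), Wnt targets (41 bp, 11 genes) and immediate early genes (43 bp, 17 genes), against 52 bp for the others. The highest were those of DNA replication genes (60 bp, 11 genes), proteasome subunits (58 bp, 20 genes), study targets (58 bp, 5 genes) and zinc finger genes (57 bp, 181 genes). In the two-sided permutation test 0 of 18 lists passed after Benjamini-Hochberg adjustment (lowest adjusted p = 0.870), and 0 had an unadjusted p under 0.05. The lowest unadjusted p, 0.0737, was that of the zinc finger genes, whose median had a 95% bootstrap interval of 53 to 65 bp. For these genes the difference was 11.5 bp where the listed 5' end lay within 10 bp of RefSeq's (permutation test, p = 0.00802, adjusted p = 0.104) and 6 bp with the reciprocal-overlap names (p = 0.0324, adjusted p = 0.583). The bootstrap intervals of immediate early genes (34 to 46 bp) and Wnt targets (29 to 48 bp) lay below 52 bp, although both had a permutation p of 0.290. In simulated data, lists of 10 genes shifted by 20 bp passed the unadjusted threshold 27 times in 100, and lists of 20 genes 65 times. After a shift of 10 bp they passed 10 and 22 times, so shifts of either size in a short list could pass unseen.

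Distances from the listed 5' end ranged widely inside every list. Those under 20 bp were more frequent where the listed start lay more than 10 bp downstream of RefSeq's than where both were the same base. Sites from 200 bp on may include background calls, as described below. Single genes at either end of a range therefore need not show the true pausing distance. Among immediate early genes KLF6 stood at 8 bp, FOS, which encodes an AP-1 subunit, at 43 bp and KLF10 at 153 bp. Heat shock genes ran from FKBP4, a co-chaperone gene, at 7 bp through BAG3 at 37 bp to HSPA8, a constitutive HSP70 gene, at 186 bp. Among elongation factors SUPT5H, which encodes the DSIF subunit SPT5, had a site at 3 bp, CDK13 at 48 bp and AFF4, a super elongation complex scaffold gene, at 285 bp. Among ribosomal protein genes RPL6 stood at 53 bp and RPL23, with the largest distance, at 243 bp. Translation factor genes ran from PABPC1 (28 bp) through EEF2 (54 bp) to EIF3D (253 bp). Wnt targets had the narrowest range of these 6 lists, from APCDD1 (8 bp) through CD44 (41 bp) to LEF1 (78 bp).

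Among the remaining lists, p53 targets ran from FDXR (38 bp) through FAS (46 bp) to RRM2B (182 bp), and oxidative phosphorylation genes from NDUFS6 (6 bp) through COX6B1 (45 bp) to NDUFB2 (263 bp). Proteasome genes ran from PSMD5 (41 bp) through PSMD1 (58 bp) to PSMA1 (299 bp), zinc finger genes from ZNF700 (3 bp) through ZNF76 (57 bp) to ZNF747 (295 bp), and splicing factors from SNRPB2 (5 bp) through SNRPC (54 bp) to SRSF8 (286 bp). DNA replication genes ran from GINS1 (5 bp) through POLA1 (60 bp) to MCM2 (261 bp), and mitosis genes from CENPE (18 bp) through BIRC5 (56 bp) to TOP2A (129 bp). Sites of cholesterol synthesis genes lay between 28 bp for INSIG1 and 192 bp for PMVK, with HMGCS1 at 48 bp. Glycolysis genes ran from ENO1 (31 bp) through HK2 (49 bp) to PKM (105 bp), and integrated stress response genes from PSAT1 (24 bp) through ASNS (43 bp) to SLC7A11 (289 bp). Colon epithelium markers ran from KRT18 (29 bp) through KRT19 (37 bp) to CDX2 (285 bp).

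**Figure D3:**
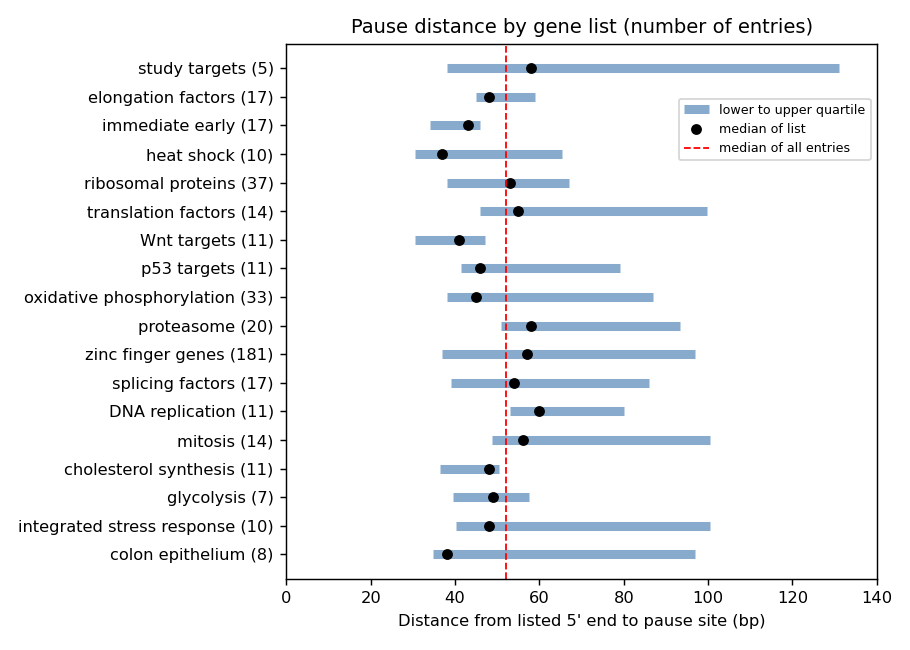
Pause distance in bp (x axis) for the 18 gene lists with at least 5 entries, with points as medians, bars from lower to upper quartile, the number of entries in brackets and the median of all entries, 52 bp, dashed. List medians lie between 37 and 60 bp, and the range between quartiles is widest for the study targets, from 38 to 131 bp.

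At the ends of the distribution, the 10 largest distances included those of CCDC90B, PSMA1 and SOWAHB at 299 bp, FNTA and SMIM19 at 298 bp, and CHKB, HOXB6, OCLN and PRR5 at 297 bp. OCLN encodes occludin, a tight junction protein. For CLIP1, DDX3Y, FGD4, FH and the unnamed entry ENSG00000197429.11, the site was on the first listed base, a distance of 0 bp. The next 5 in order of symbol, ACP7, CEP126, RTEL1, SEC31A and TM4SF19, stood at 1 bp. FH encodes fumarate hydratase of the citric acid cycle.

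The listed 5' ends often differed from the outermost RefSeq start of the same gene, and the pause distance differed between classes of that difference. Both ends were the same base in 25.8% of the 5822 named genes (95% Wilson interval 24.7 to 27.0%), and they lay within 10 bp in 39.9% and within 50 bp in 64.0%. The listed end lay more than 10 bp downstream in 53.2% and more than 10 bp upstream in 6.85%. In the 177 genes whose listed end lay 11 to 50 bp upstream of the RefSeq start, the median pause distance was 76 bp (95% bootstrap interval 71 to 87), 25 bp more than in the other named genes. In the 1224 genes whose listed end lay 11 to 50 bp downstream, it was 49 bp (47.5 to 51), 4 bp less than in the others.

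By two-sided permutation tests with Benjamini-Hochberg adjustment over 8 classes of offset, the former difference had an adjusted p of 8e-05, from the smallest p that 100000 resamples can give (1e-05), and the latter 0.0114. The classes over 50 bp upstream (57.5 bp, 222 genes) and over 300 bp downstream (54 bp, 1180 genes) also passed the permutation test, both with an adjusted p of 0.0492, close to the threshold. These classes were formed after the data were seen. Offset and pause distance share the listed 5' end, so for a fixed pause site a listed end farther upstream lengthens the distance by construction, and the test does not separate this from a difference in the sites. Among the 3726 genes whose ends lay within 50 bp of each other, the distance to the pause site had an interquartile range of 40 bp from the listed end and 46 bp from the RefSeq end, a difference of 6 bp (95% bootstrap interval 4 to 8). Among the 4511 genes within 300 bp the ranges were 41 and 67 bp, a difference of 26 bp (23 to 29.5), so its size depends on the limit. The listed distances never exceed 299 bp, whereas the RefSeq-based ones have no such bound.

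**Figure D4:**
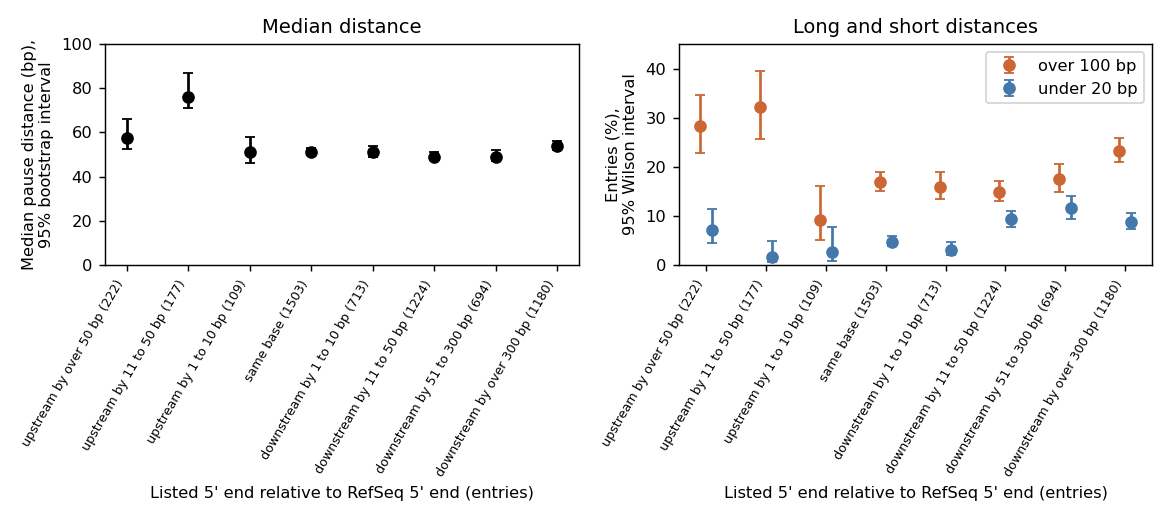
Median pause distance in bp with 95% bootstrap intervals (left) and share of genes, in %, with distances over 100 bp or under 20 bp with 95% Wilson intervals (right), by the position of the listed 5' end relative to the RefSeq 5' end (x axis, number of genes in brackets). The class 11 to 50 bp upstream has the highest median, 76 bp, and the largest share over 100 bp, 32.2%.

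Pause sites lay inside the extent of their RefSeq gene in 96.6% of named genes (5624 of 5822, 95% Wilson interval 96.1 to 97.0%) and upstream of it in the remaining 198 genes. A second RefSeq gene covered the site in 12.8% (747 genes), a long noncoding RNA gene in 8.86% and another protein-coding gene in 3.78%. Exons, introns and untranslated regions at the sites were not assigned here.

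Gene length showed no detectable relation to pause distance across the 6481 genes, which are not independent replicates. Pearson's r with log10 length was -0.0109 (permutation p = 0.380) and Spearman's rho was -0.0163 (permutation p = 0.190). It was the only such relation computed, so the adjusted values equal these. The median was 53 bp in the shortest 1621 genes (3005 to 15771 bp) and 51 bp in the longest 1620 (80641 to 1504176 bp).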

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

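The median pause distance stayed at 52 bp for distances of 1 to 300 bp, on either strand, for 1 entry per symbol and for named genes alone. It was 51 bp where the listed 5' end lay within 10 bp of RefSeq's. The range of 1 to 300 bp dropped only the 5 genes at 0 bp, so it could hardly move this or any result below. The lists hold each gene once, so 1 entry per symbol removed nothing. No gene list tested passed the distance test under the alternatives run: the lowest adjusted p of the permutation tests was 0.691 with means, 0.870 for 1 to 300 bp, 0.583 with the reciprocal-overlap names and 0.104 for 5' ends within 10 bp of RefSeq, where zinc finger genes exceeded the others by 11.5 bp (unadjusted p = 0.00802). In that last setting 13 of the 18 lists kept 5 entries and were tested, and study targets, heat shock, p53 targets, DNA replication and glycolysis were not. Of the 21 membership tests, 15 passed in the main setting, 19 against all RefSeq genes (13 of the main calls kept), 12 against genes of at least 3005 bp (12 kept), 15 against such genes without a protein-coding neighbour within 1000 bp (12 kept) and 12 with the reciprocal-overlap names (12 kept). The isolated background and the second naming rule were chosen after seeing the data. Fibroblast and blood markers lost their calls against all RefSeq genes (Fisher's exact test, adjusted p = 0.621 each). Most genes of that background are not protein coding, while all named entries are, so calls gained there reflect biotype and do not strengthen the result. No call turned to the opposite direction under these settings. Differences that passed no test did change sign: with means in place of medians 6 lists did so, among them colon epithelium (from -14 to 14.3 bp) and the integrated stress response (from -4 to 13.2 bp). With 5' ends within 10 bp of RefSeq 2 lists did, among them oxidative phosphorylation (from -7 to 8 bp), and with the reciprocal-overlap names 2, among them p53 targets (from -6 to 7 bp). Membership of colon epithelium went from 0.73 to -0.02 (log2 odds ratio) against genes without a close neighbour. The lowest adjusted p among these was 0.724. Spearman's rho with length was -0.0158 for 1 to 300 bp. Measured against any RefSeq gene in place of the matched one, 97.3% of the pause sites of named entries lay inside a gene. Of the 5' ends of named entries, 40.2% lay within 10 bp of a gene end of either kind. No paired analysis was possible because the lists hold no value for any library, and for that reason no replicate could be left out. Settings with GC-matched genes, other flanks, shifted bases, wider promoter windows, other GC windows and single transcripts were not run, as they need a sequence, transcript models or strands not used here. The depth behind each pause site is unknown, so weakly supported sites cannot be set apart.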

Other observations

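All tests in this part were chosen after the data were seen. Gene families not described above also differed in how often they were listed, against RefSeq protein-coding genes of at least 3005 bp (two-sided Fisher's exact tests, Benjamini-Hochberg adjusted over 20 families, 11 passing). By Fisher's exact test 3 were listed more often: ubiquitin-specific proteases (26 of 48, 54.2%, adjusted p = 0.00496), RAB GTPases of vesicle traffic (31 of 61, 50.8%, adjusted p = 0.00878) and mitochondrial ribosomal proteins (30 of 64, 46.9%, adjusted p = 0.0278). Another 8 were listed less often. Olfactory receptors had 0 of 194 genes (95% Wilson upper bound 1.94%, Fisher's exact test, adjusted p = 2.94e-32), protocadherins 1 of 65, collagens 1 of 44 and chemokines 1 of 21. Potassium channels had 10 of 91, keratins 4 of 54, cytochromes P450 7 of 55 and interleukins 4 of 34. HOX genes (7 of 24), solute carriers (110 of 337), kinesins (17 of 43) and ABC transporters (13 of 45) did not pass, nor did claudins (2 of 13), integrins (7 of 30), TRIM genes (26 of 67), DEAD-box helicases (13 of 30) and the E2F and MYC family (10 of 17). The family tests took no account of close or overlapping neighbours. Genes that share a 3' end could not be named by the rule used, and unnamed genes were counted as not listed. Low shares in families of clustered genes may therefore reflect the spacing of the list or the naming rule.

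Of 13 families with at least 5 entries, 0 passed the permutation test of pause distance after adjustment and 1 had an unadjusted p under 0.05. That family, the solute carriers, had a median of 59.5 bp in 110 genes against 52 bp in the others (permutation test, unadjusted p = 0.0285, adjusted p = 0.370). By chromosome, 2 of 24 passed, both listed less often. Of RefSeq protein-coding genes of at least 3005 bp, 26.5% on chromosome 19 and 24.4% on chromosome X were in the list. Over all chromosomes 5822 of 18094 were (Fisher's exact test, adjusted p = 4.61e-05 for each). Close neighbours were not taken into account in this test. One distance held more sites than its surroundings: 13 genes stood at 230 bp, against a mean of 2.85 over the 20 neighbouring distances (exact Poisson test, adjusted p = 0.00266 over 280 distances).

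Pause distances over 100 bp, in 1210 genes, may reflect starts placed upstream of the one in use, sites called at random within the window, or pausing farther downstream. The tail was not limited to genes whose listed and RefSeq 5' ends differ. With the same base at both, 16.97% (95% Wilson interval 15.2 to 18.9%) of genes were over 100 bp, against 19.1% of other named genes. With the listed end upstream, the share was 9.17% at 1 to 10 bp, 32.2% at 11 to 50 bp and 28.4% beyond. With it downstream, the share was 15.99%, 14.95% and 17.6% at 1 to 10, 11 to 50 and 51 to 300 bp, and 23.3% beyond. The RefSeq end is the outermost start, which need not be in use. These shares therefore do not test whether listed starts lay upstream of the start in use. An even spread of sites over the window cannot account for the sites from 100 to under 150 bp, which were 3.46 times as many as from 250 bp on (568 against 164, exact binomial p = 5.76e-53). From 200 bp on the counts per 10 bp did not depart from an even spread (23 to 42 per bin, chi-square p = 0.498). Bins of that width do not show the excess at the single distance of 230 bp given above. The rate from 200 bp on, 3.45 sites per bp, would give 1035 sites (15.97% of all) over 300 bp if it held throughout. Whether those sites are background calls or distant pausing stays open, and no biological explanation was tested.

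Distances under 20 bp, shorter than most, were unevenly spread over genes. Where the RefSeq start lay 11 to 300 bp upstream of the listed one, 10.1% of 1918 genes had such a site, against 4.79% where both were the same base, a ratio of 2.11 (two-sided Fisher's exact test, p = 5.16e-09). This would be seen if some listed starts lay downstream of a start in use, so that the true distance would be longer. Offset and distance share the listed 5' end, so the test does not separate this from a difference in the sites. Of the 414 named genes under 20 bp, 194 had the RefSeq start 11 to 300 bp upstream and 104 had it farther upstream (8.81% of 1180 genes, 95% Wilson interval 7.33 to 10.6%). With the listed start only 1 to 10 bp downstream, the share was 3.09% of 713 genes, not higher than at the same base. Where the listed start was the upstream one, the share was 2.75% of 109 genes at 1 to 10 bp, 1.69% of 177 at 11 to 50 bp and 7.21% of 222 beyond (4.48 to 11.4%), and no biological explanation was tested.

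Listed genes stand apart from each other, although 1186 of the 5822 named ones had another protein-coding gene overlapping or within 1000 bp. Only 1 pair of neighbouring entries was under 1000 bp apart and none overlapped, while 100 random draws of as many RefSeq genes of that length gave 482 to 590 such pairs. A list made with no selection on neighbouring genes therefore cannot account for the spacing, and no biological explanation was tested. The selection may bear on which pathways appear: among genes with no protein-coding neighbour within 1000 bp, 14 of 15 splicing factors, 7 of 7 heat shock genes and 9 of 11 DNA replication genes were listed (Fisher's exact test, adjusted p = 0.000256, 0.00534 and 0.0168), lists that did not pass against all protein-coding genes, while Wnt targets (0.0780), zinc finger genes (0.0700) and histones (0.538) lost their calls and the total stayed at 15.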
